A study of Drosophila melanogaster with 2 samples.

How the data were processed

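ChIP-seq of Su(var)2-HP2-GFP with an antibody against GFP was analysed from whole Drosophila melanogaster embryos aged 0 to 10 h, in 1 group of 2 biological replicates that carry the numbers 4 and 6 in the labels. Chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The 4 deposited peak lists were used. Per the file listing deposited with the samples, each replicate's list was made from that replicate's alignment and a common control alignment, the pooled list from both alignments and the control, and the IDR list from both replicate lists and the pooled list. The build is dm6, per the labels. The aligner and the peak caller are not given in the sources used here. The control reads are not analysed here.

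The signal value of each deposited peak is a score from the peak calling with the control, on a scale that the sources used here do not state. The deposited lists also give −log10 of a q-value per peak, with a highest possible value of 3.98 in the pooled list, 3.94 for replicate 4 and 3.97 for replicate 6. All 2006 IDR peaks have that highest value, so q-values do not rank them. The signal values are the authors' and were used to rank peaks within a list. The replicate and pooled lists stop at 30000 peaks, and 12389 pooled peaks have a q-value under 0.05, so the lower part of each list holds weak calls. Every IDR peak is a row of the pooled list, and the IDR list equals the 2006 pooled peaks of highest signal value. The IDR peaks fall into 1735 separate intervals, since some called intervals hold several summits, and each summit was counted as a peak. To compare replicates, the signal value was divided by the median of the 2006 strongest peaks of the same list (relative signal), and values are given as mean ± SD of the 2 replicates. No read numbers are in the files, so depth is unknown and no interval for it was computed.

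Peaks were placed by their summit. Start sites, genes and transposable elements came from the Ensembl release 115 annotation and sequence from the RefSeq assembly of the same chromosomes, whose soft-masked bases were taken as repeats. Pericentromeric parts were set as the ends of 2L beyond 22 Mb, 3L beyond 23 Mb and X beyond 22 Mb, and the starts of 2R up to 5.4 Mb and 3R up to 4.2 Mb. These are rounded approximations, and some peaks counted on the arms lie close beyond them. A peak was counted at a promoter when its summit was within 500 bp of a start site of any gene other than a transposable element.

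Shares of IDR peaks were compared with the 27994 other pooled peaks by two-sided Fisher's exact tests, with Wilson 95% intervals for shares and log-normal intervals for odds ratios, and with random places in non-N sequence. For the 2 replicates the same shares were taken from the 2006 strongest peaks of each list. Overlap was counted as summits within 100 bp. The 20 gene lists were tested by Fisher's exact test against all other protein-coding genes, and the 18 motifs by an exact McNemar test of the 100 bp on each side of the summit against a window 1 kb to a side drawn at random, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Medians of log2 signal and means of soft-masked shares were compared by permutation tests with 100000 resamples. Where a count was 0, the share that 3 counts would give is the upper limit. Through synonyms, 19 list symbols were matched to current symbols, and 13 symbols were not used here. Genes that share a promoter share its peak and are not independent.

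Named genes followed a rule set before the data were examined: the genes nearest to the 25 strongest IDR peaks, up to 4 members of each list with the strongest promoter peak, the 8 strongest genes each of chromosome 4 and the pericentromeric parts, and Su(var)2-HP2 itself. Groups, lists, motifs, borders, tests and most alternatives were also fixed then. The alternatives were a stricter peak set (the upper 1003 IDR peaks), IDR peaks among the strongest of both replicates, each replicate left out, the surroundings of Su(var)2-HP2 left out, other distances, borders moved by 0.5 Mb, other overlap rules and other backgrounds. Comparisons of genes by part of the genome, gene lists on the arms only, signal within each part, transposable elements by start-site class, pairing on GC content and a second draw of the motif flanks were added after the data were examined. The second flank draw arose when the script was revised after the first motif results had been seen; the first draw was kept for the reported values.

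The tests of shares, gene lists, start-site assignment, motifs against flanks, signal, soft-masked share and replicate overlap were run on simulated data with known answers. The correlations, the cluster draws, the count at Su(var)2-HP2, the match ratio of low-ranked calls and the matched-peak motif test were not. For shares, a planted odds ratio of 2 came back as 1.98, and 5% of runs with no difference passed the threshold. For gene lists, 98.5% of lists with a planted share of 40% were recovered among 13968 genes, and 0.5% of the lists with nothing planted were called. For motifs, a site planted at 5% of 2006 summits was called in 100% of 20 runs, and 0.938% of the motifs that were not planted were called. The simulated summits and flanks had the same base composition, and the simulated peaks and genes of the share and list tests were independent. These rates of false calls therefore do not cover differences in base composition, summits that share an interval or genes that lie close together. The computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.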

Results

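Su(var)2-HP2 is a heterochromatin protein of Drosophila melanogaster that binds HP1, a structural protein of silent chromatin. Its binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos aged 0 to 10 h. The embryos came from a transgenic line that expresses Su(var)2-HP2 with GFP at its C terminus, and the immunoprecipitation used an antibody against GFP. The series holds 1 group of 2 biological replicates, which the labels number 4 and 6. Each replicate has a list of 30000 peaks, and a pooled list from both replicates has 30000 peaks. A list with a threshold on agreement between replicates (irreproducible discovery rate, IDR) has 2006 peaks. It equals the 2006 pooled peaks of highest signal value, so a single IDR peak need not be found in both replicates. Of the IDR peaks, 1893 had a matched summit in both replicate lists, and 67.2% were among the 2006 strongest peaks of both. Positions are in the dm6 build. The files give no read numbers, so the sequencing depth is unknown, and the intervals given for shares of peaks or genes cover counting error only. With a single group, the comparisons are between parts of the genome and between the replicates.

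The strongest Su(var)2-HP2-GFP peaks lay at start sites of genes in pericentromeric DNA and on chromosome 4, the small, HP1-rich chromosome. Of the 25 IDR peaks with the highest signal value, 18 were pericentromeric, 7 were on chromosome 4 and 0 were on the chromosome arms. The summits of 24 of them lay within 500 bp of an annotated start site. The highest peak was at MED21 (FBgn0040020), which encodes a Mediator subunit, with a summit at position 25116009 of 3L, 63 bp from the start site. Its signal value was 5544, and its signal relative to the median of the 2006 strongest peaks of the same list was 26.6 ± 6.23 (SD, n = 2 replicates). RpL5 (FBgn0064225), a ribosomal protein gene, had a summit in its 5' UTR at position 22536830 of 2L with a relative signal of 21.7 ± 5.76 (SD, n = 2). The summit at position 5363239 of 2R, between the divergent genes CG10417 and lncRNA:CR42646, had a relative signal of 21.3 ± 0.191 (SD, n = 2).

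The other pericentromeric genes among these 25 peaks were CG40191, the RNA helicase gene Dbp80, Yeti, lncRNA:CR43765 with its neighbour Nubpl, d4, CG33217, CG17683, UQCR-11 of the mitochondrial respiratory chain, CG17486, the mitochondrial import gene Tim17b, the kinase gene Haspin, the splicing factor gene Spf30, RpL15, CG17528 and CG40045. Their relative signals ran from 21.1 ± 2.44 at CG40191 to 15.2 ± 0.0177 at CG17528 (SD, n = 2). Haspin was the exception to the start-site position, with a summit 1323 bp from its nearest start site. The MED21 and UQCR-11 summits shared 1 called interval of 6834 bp on 3L, from 25115204 to 25122037. All 25 peaks ranked 37 or higher in the list of replicate 4 and 34 or higher in that of replicate 6. At each of them except CG17486, relative signal was higher in replicate 6, for example 31 against 22.2 at MED21. The SD values there thus hold a difference between replicates that mostly has the same direction.

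**Figure D1:**
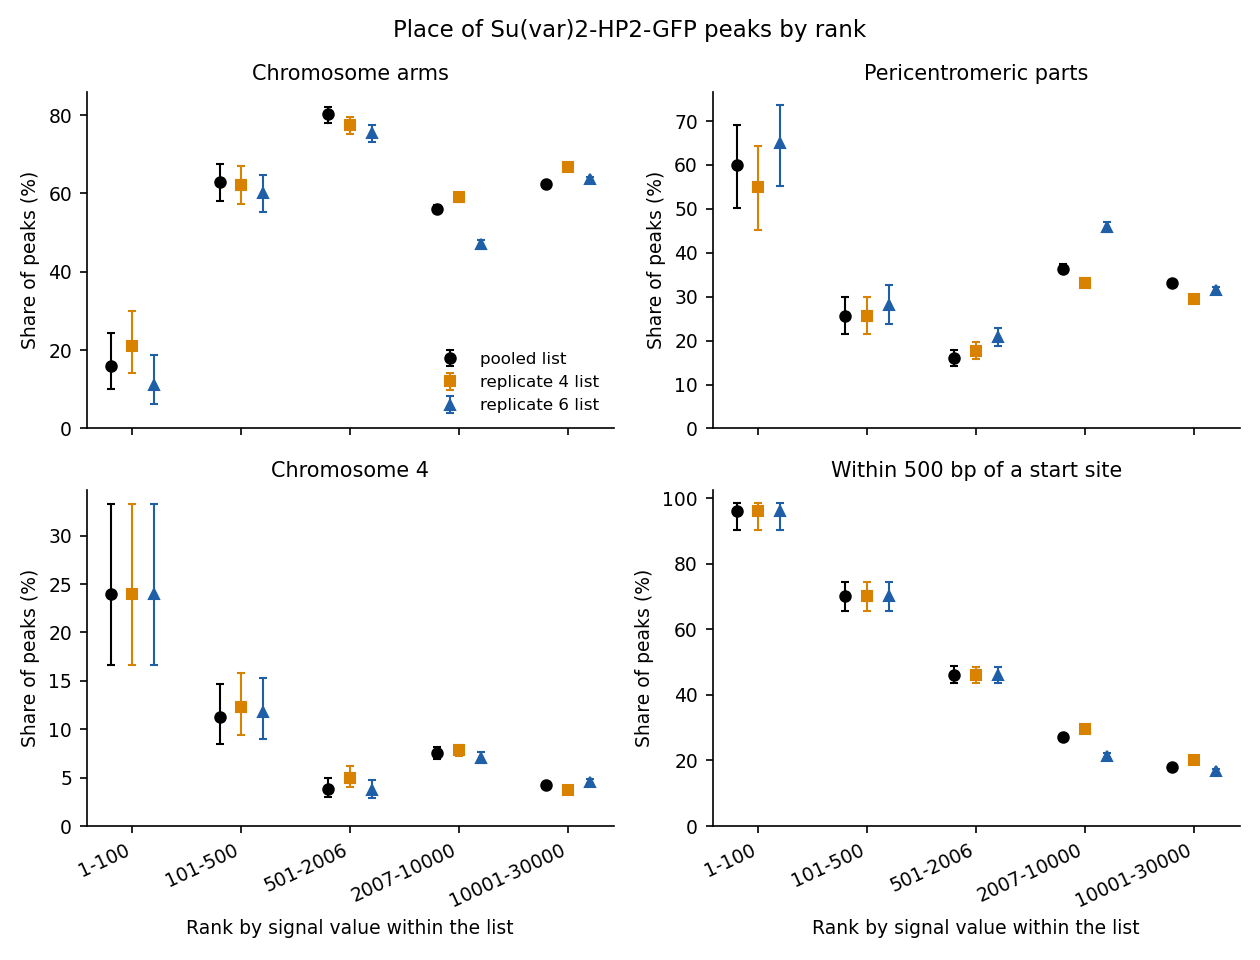
Share of peaks (%) on the chromosome arms, in the pericentromeric parts, on chromosome 4 and within 500 bp of a start site, by rank of signal value (x axis) in the pooled list and each replicate's list; bars are Wilson 95% intervals. Among the 100 strongest pooled peaks, 60 were pericentromeric and 24 were on chromosome 4, and in each of these 3 lists 96 of the 100 strongest were within 500 bp of a start site.

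Chromosome 4 was densely marked. It makes up 0.98% of the assembled chromosomes and carried 127 of the 2006 IDR peaks, 6.33% (Wilson 95% interval 5.35 to 7.48), or 94.2 peaks per Mb against 12.9 per Mb on the chromosome arms. In the 2006 strongest peaks of each replicate the share was 6.85% ± 0.74 (SD, n = 2). Random places fell on chromosome 4 in 0.879% of draws. The rest of the pooled list, 27994 peaks, held 5.18% of its peaks there, an odds ratio of 1.24 for the IDR peaks (95% interval 1.03 to 1.49, two-sided Fisher's exact test, p = 0.0295). The size of this difference depended on the peak set. It was not past the threshold without replicate 4 (odds ratio 1.21, Fisher's exact test, p = 0.0509), and the odds ratio was 1.55 without replicate 6, 1.47 for IDR peaks among the strongest of both replicates and 1.94 for the upper 1003 IDR peaks (Fisher's exact test, p = 2.69e-08 for the last). The 2006 IDR peaks fall into 1735 separate intervals and the 30000 pooled peaks into 23249. Summits of the same interval were counted as independent peaks here and in the other shares and densities of peaks. The p-values and intervals for shares of peaks may thus overstate the certainty, and no count by interval was made for each part.

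Gyf (FBgn0039936), a translational regulator, had the highest chromosome 4 peak, with a summit at position 867144, 119 bp from its start site, and a relative signal of 20.7 ± 2.51 (SD, n = 2). The semaphorin receptor gene PlexA (position 1027260) followed at 18.4 ± 2.54, the ephrin receptor gene Eph at 18.3 ± 0.961 and pho, which encodes a DNA-binding Polycomb group protein, at 17.6 ± 2.97 (SD, n = 2). RpS3A, anne, Arl4 and the kinase gene CaMKII ranged from 16.7 ± 1.63 to 14.5 ± 0.101. The segmentation gene ci, near the left end of the chromosome, had a much lower value of 1.12 ± 0.103 (SD, n = 2). Of the 80 protein-coding genes of chromosome 4, 51 had an IDR summit within 500 bp of a start site, 63.8% (Wilson 95% interval 52.8 to 73.4), and the replicates' own strongest peaks gave 65.6% ± 6.19 (SD, n = 2).

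**Figure D2:**
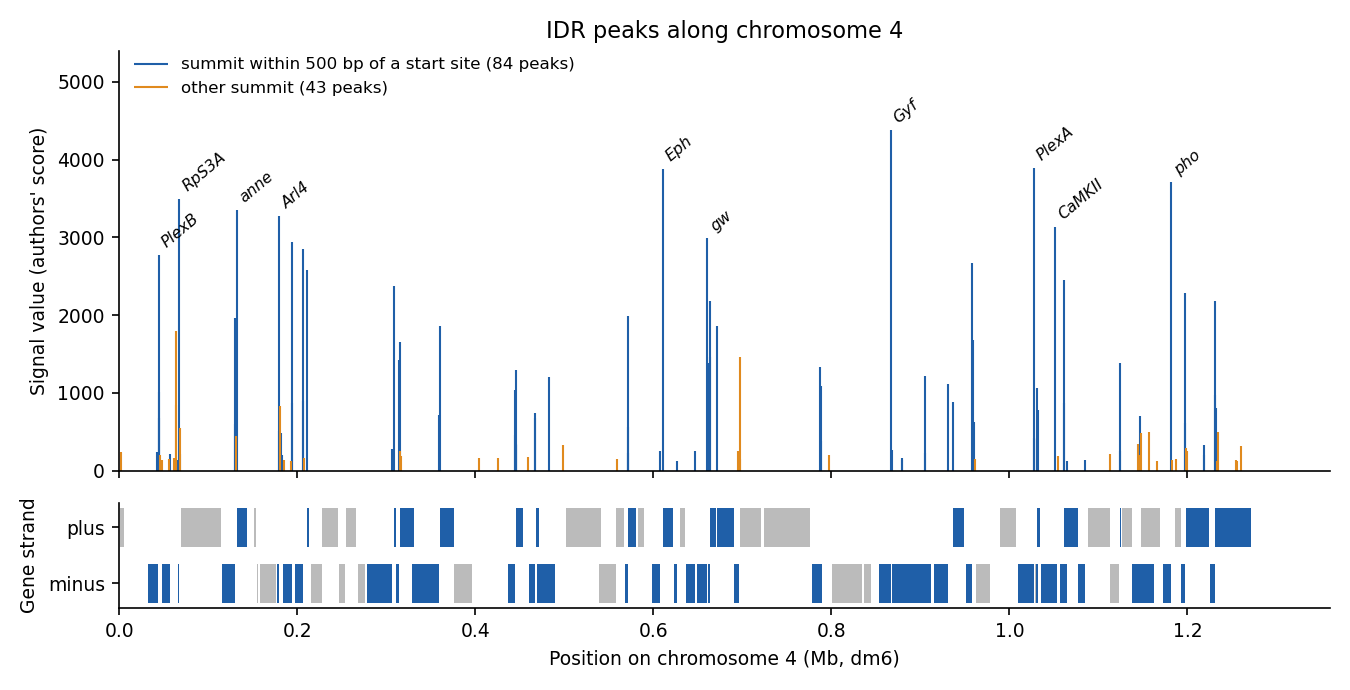
Signal value (the authors' score, upper y axis) of the 127 IDR peaks along chromosome 4 (x axis, Mb in dm6), with summits within 500 bp of a start site in blue and others in orange; the lower track shows protein-coding genes by strand, in blue where a summit lies within 500 bp of a start site. The 84 peaks near start sites had a median signal value of 867 and the other 43 a median of 192.

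Pericentromeric parts of 2L, 2R, 3L, 3R and X held 402 IDR peaks, 20% of the list (Wilson 95% interval 18.3 to 21.8), or 22.6 peaks per Mb. Their share in the 2006 strongest peaks of each replicate was 22.7% ± 2.4 (SD, n = 2). The direction of the comparison depended on the background. Random places fell there in 12.7% of draws, so that the IDR peaks were enriched (odds ratio 1.72, 95% interval 1.53 to 1.93, two-sided Fisher's exact test, p = 1.14e-18). The rest of the pooled list held 34.1% of its peaks there, so that the IDR peaks were depleted within that list (odds ratio 0.484, 95% interval 0.433 to 0.541, two-sided Fisher's exact test, p = 3.05e-41). By rank, the pericentromeric share was 60% in the 100 strongest pooled peaks, 25.5% at ranks 101 to 500, 15.9% at ranks 501 to 2006 and 36.3% at ranks 2007 to 10000.

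Genes in pericentromeric DNA had promoter peaks more often than genes of the arms. Of 193 pericentromeric protein-coding genes, 88 had an IDR summit within 500 bp of a start site, 45.6% (Wilson 95% interval 38.7 to 52.6), against 1096 of 13672 arm genes, 8.02% (7.57 to 8.48). The odds ratio was 9.62 (95% interval 7.2 to 12.9, two-sided Fisher's exact test, p = 2.7e-43), and for chromosome 4 against the arms it was 20.2 (12.7 to 32, p = 1.66e-35). Per replicate the pericentromeric value was 45.1% ± 2.2 and the arm value 7.77% ± 0.207 (SD, n = 2). These comparisons by gene were added after the data were examined. The Y chromosome carried 2 IDR peaks, and 0 of its 23 protein-coding genes had a promoter peak, which allows a share of up to 13%. The called intervals of the peaks were also wider off the arms. With each interval counted once per summit, the median width was 319 bp on the arms, 1133 bp in pericentromeric parts and 1875 bp on chromosome 4. Intervals with several summits thus weigh more in these medians.

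Across the whole IDR list, 1072 of 2006 summits lay within 500 bp of a start site, 53.4% (Wilson 95% interval 51.3 to 55.6), against 20.7% of the rest of the pooled list (odds ratio 4.39, 95% interval 4.01 to 4.82, two-sided Fisher's exact test, p = 4.63e-209). Random placement on the same chromosomes gave a mean of 13.6%, and the highest of 1000 placements gave 15.8%. Both replicates gave nearly the same share, 53.4% ± 0.0352 (SD, n = 2), which by itself is no measure of the error. Of the remaining IDR summits, 504 were in introns, 372 were intergenic, 12 were in coding exons and 15 in 3' UTRs. The start-site share was 57.8% on the arms, 33.8% in pericentromeric parts and 66.1% on chromosome 4, against 32.3%, 2.3% and 7.1% of the other pooled peaks of the same parts.

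Signal values were higher at start sites. The median signal value was 240 for the 1072 IDR peaks near start sites and 179 for the other 934, a difference of 0.42 on the log2 scale (two-sided permutation test over peaks with 100000 resamples, p = 1e-05, the smallest they can give). The difference was 0.53 in replicate 6 alone and 0.38 in replicate 4 alone. Its size depended on the part of the genome: within pericentromeric parts it was 2.95 on the log2 scale, within chromosome 4 it was 2.18 and within the arms 0.25, each with the same permutation p and each added after the data were examined. Peaks are not replicates, and the p-values describe these lists only.

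The gene lists fixed before the data were examined were compared with all other protein-coding genes, of 13968 in total. Promoter peaks were found at 22 of 30 chromosome 4 landmark genes and at 26 of 36 pericentromeric landmark genes, 73.3% and 72.2% (odds ratios 28.8 and 27.4, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 1.64e-16 and 6.8e-19). These lists were defined by position. Cytoplasmic ribosomal protein genes had promoter peaks at 38 of 93 members, 40.9% (Wilson 95% interval 31.4 to 51), with an odds ratio of 7.32 (Fisher's exact test, adjusted p = 5.21e-16). RpL5, RpL15 and RpS3A are heterochromatic members, and RpS27A, at position 10408229 of 2L, was the strongest arm member with a relative signal of 13.2 ± 0.674 (SD, n = 2). The RpS27A summit was also within 500 bp of a start site of Ip259. On the arms alone the count was 32 of 87 (odds ratio 6.85, Fisher's exact test, adjusted p = 8.35e-13). The count differed between replicates: 46 of 93 members had a summit among the strongest peaks of replicate 4 (odds ratio 11) and 21 of 93 among those of replicate 6 (odds ratio 3.08), and both calls passed the threshold.

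Insulator and architectural protein genes had promoter peaks at 7 of 21 members (33.3%, odds ratio 5.18, Fisher's exact test, adjusted p = 0.00455). The strongest were the cohesin subunit gene vtd at 13.1 ± 0.964, Clamp at 12.8 ± 0.343 and the cohesin loader gene Nipped-B at 11.4 ± 0.0895, all 3 pericentromeric, followed by Chro on 3L at 4.26 ± 0.159 (SD, n = 2). The vtd, Clamp and Chro summits were also within 500 bp of start sites of lncRNA:CR45181, lncRNA:CR44809 and Ssl1, respectively. Among arm members the count was 4 of 18, which did not pass (odds ratio 3.29, Fisher's exact test, adjusted p = 0.121), and neither did the list among genes with any pooled-list summit near a start site (odds ratio 2.57, adjusted p = 0.163). Mitochondrial ribosomal protein genes had promoter peaks at 13 of 73 members (17.8%, odds ratio 2.25, Fisher's exact test, adjusted p = 0.0302), led by mRpS7, which shares its peak with the mitotic kinase gene Cdk1, at 12.3 ± 0.407. This call was lost without replicate 6 (Fisher's exact test, adjusted p = 0.0562), in the upper 1003 IDR peaks (0.0546), in IDR peaks among the strongest of both replicates (0.0568), with a summit anywhere in the gene (0.106) and among genes with a pooled-list summit (odds ratio 1.43, adjusted p = 0.447). Proteasome subunit genes had promoter peaks at 2 of 48 members, Prosalpha6 at 12.6 ± 1.27 and Prosbeta1 at 0.599 ± 0.203 (SD, n = 2). The Prosalpha6 summit lay 148 bp from its start site and 13 bp from that of Npc1a. This list did not pass against all other genes (odds ratio 0.447, Fisher's exact test, adjusted p = 0.516) and was not compared with the ribosomal protein lists. Without replicate 6 that odds ratio was 0.983, and the Prosbeta1 peak ranked 3043 in replicate 6.

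**Figure D3:**
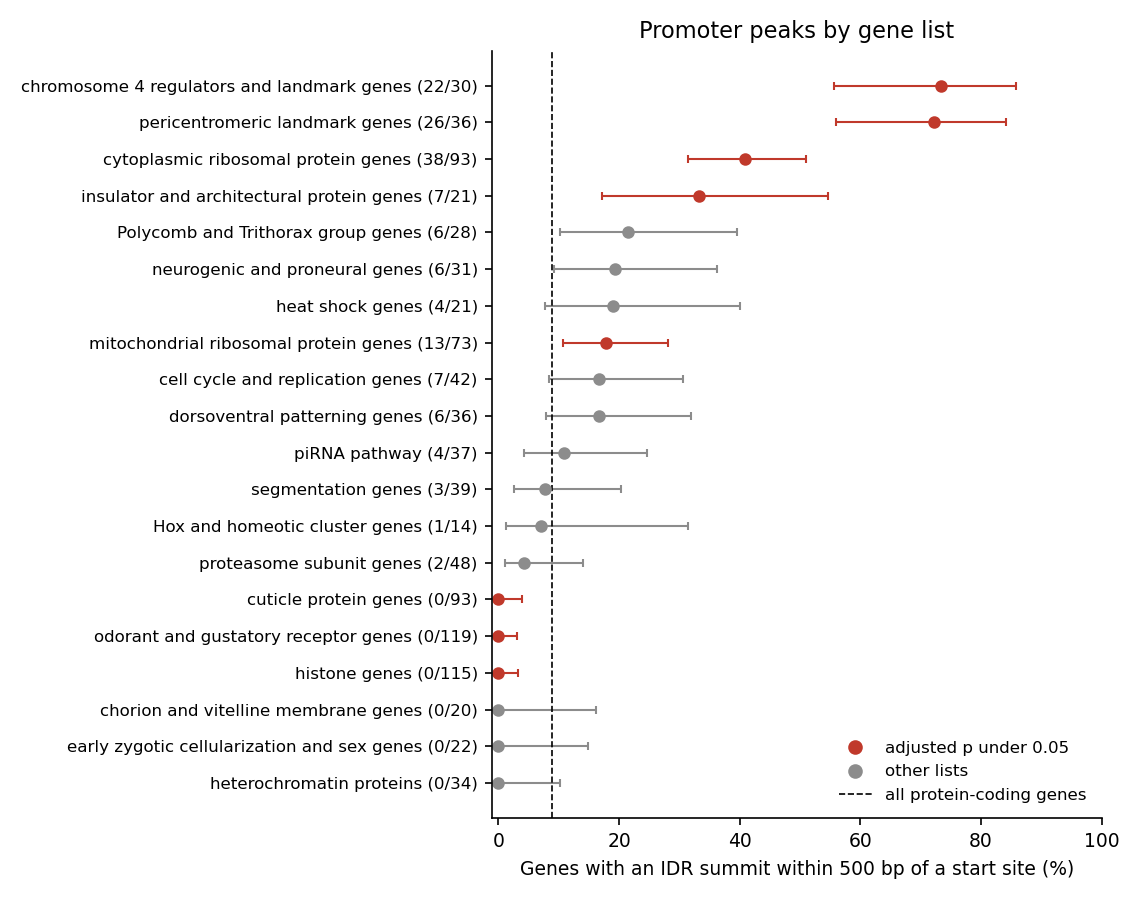
Share of genes (%, x axis) with an IDR summit within 500 bp of a start site for the 20 gene lists (y axis, members with a peak over members), with Wilson 95% intervals; red points passed an adjusted p of 0.05 and the dashed line is the share of all protein-coding genes, 8.84%. The position-defined lists stand at 73.3% and 72.2%, and cytoplasmic ribosomal protein genes at 40.9%.

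Chemoreceptor, cuticle and histone genes had no promoter peaks. The count was 0 of 119 odorant and gustatory receptor genes, 0 of 93 cuticle protein genes and 0 of 115 histone genes, which allows shares of up to 2.52%, 3.23% and 2.61% (Fisher's exact test, adjusted p = 0.000138, 0.00108 and 0.000167). The histone genes lie in near-identical repeated copies, where reads may not be placed uniquely, so their 0 is not a clear absence. Chorion and vitelline membrane genes had 0 of 20 and early zygotic cellularization and sex genes 0 of 22, and neither list passed (Fisher's exact test, adjusted p = 0.318 for both). Genes for heterochromatin proteins, Su(var)2-HP2 itself among them, had 0 of 34, which allows a share of up to 8.82% and did not pass against all genes (odds ratio 0.149, Fisher's exact test, adjusted p = 0.127). Against genes with any pooled-list summit near a start site, this list was lower (odds ratio 0.0761, Fisher's exact test, adjusted p = 0.0292). Without replicate 4 the odds ratio of the heterochromatin protein list against all genes was 0.316. With a summit anywhere in the gene its direction turned, with 5 of 34 members, 14.7% (odds ratio 1.31, Fisher's exact test, adjusted p = 0.653). Gene length was not matched in that setting. Among genes with a pooled-list summit only 7 receptor genes remained, 0 of them with an IDR summit, and their call was lost (Fisher's exact test, adjusted p = 0.531). The cuticle and histone lists had fewer than 5 members left there and were not tested.

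Lists of developmental regulators were compared with all other protein-coding genes and not with each other; the share of all genes was 8.84%. Segmentation genes had promoter peaks at 3 of 39 members and Hox and homeotic cluster genes at 1 of 14, 7.69% and 7.14%. Dorsoventral patterning genes had 6 of 36 (16.7%, odds ratio 2.07), neurogenic and proneural genes 6 of 31 (19.4%, odds ratio 2.48) and Polycomb and Trithorax group genes 6 of 28 (21.4%, odds ratio 2.82). None of these 5 lists passed with the IDR list and 500 bp (Fisher's exact test, adjusted p from 0.0729 to 1), but 3 passed under other settings. With a summit anywhere in the gene, the counts were 13 of 28 Polycomb and Trithorax group genes (odds ratio 6.63, Fisher's exact test, adjusted p = 1.57e-05), 13 of 36 dorsoventral genes (odds ratio 4.32, adjusted p = 0.000297) and 9 of 31 neurogenic genes (odds ratio 3.12, adjusted p = 0.0142). Genes were not matched on length, and a longer gene has more room for a summit in this setting, so these calls may reflect gene length. The Hox list turned direction there without passing, with 4 of 14 (odds ratio 3.04 against 0.793 at start sites, Fisher's exact test, adjusted p = 0.108). The Polycomb and Trithorax list also passed in the upper 1003 IDR peaks (Fisher's exact test, adjusted p = 0.0318), in those among the strongest of both replicates (0.0224) and within 1000 bp (0.012), and the neurogenic list in the same 2 peak sets (0.0379 and 0.0329) and with either replicate alone (0.0347 and 0.033). Within 250 bp the neurogenic count was 2 of 31 and the direction turned (odds ratio 0.887). Among genes with a pooled-list summit none of the 3 passed (odds ratios 1.24, 1.8 and 1.41). The odds ratio of the segmentation list fell from 0.859 to 0.564 without replicate 4.

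Named members were cact, the inhibitor of Dorsal, at 5.12 ± 0.437, ph-p at 3.82 ± 0.549, the chromatin remodeller gene mor at 2.45 ± 0.476, E(spl)m7-HLH at 2.36 ± 0.0535, E(spl)mdelta-HLH at 2.23 ± 0.0937, numb at 1.86 ± 0.403, the Hox cofactor gene exd at 1.83 ± 0.46, elav at 1.67 ± 0.1 and E(z), which encodes a histone methyltransferase, at 1.47 ± 0.546 (SD, n = 2). Further named members were mthl1 at 1.95 ± 0.0355, stumps at 1.71 ± 0.209, tin at 0.893 ± 0.15 and nkd at 0.827 ± 0.178 (SD, n = 2). Several of these summits also lay within 500 bp of start sites of other genes. These were eIF5 and CG46312 at exd, Hel89B at mor, Cnep1r2 at E(z), CG43116 at E(spl)mdelta-HLH, lncRNA:enrr at elav and SNRPG at mthl1. For fkh the replicates differed, with rank 795 in replicate 4 and rank 10722 in replicate 6. The piRNA pathway had 4 of 37 members (Fisher's exact test, adjusted p = 0.628), led by the germline helicase gene vas at 5.5 ± 0.952, and heat shock genes had 4 of 21 (Fisher's exact test, adjusted p = 0.167), led by Hsc70-4 at 4.59 ± 0.0862. Cell cycle and replication genes had 7 of 42 (Fisher's exact test, adjusted p = 0.156), with mei-41 at 2.98 ± 0.458 and CycD at 2.89 ± 0.208 after Cdk1. The vas, Hsc70-4 and mei-41 summits were also within 500 bp of start sites of solo, tefu and TH1, respectively.

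Sequence motifs of broadly active promoters were more frequent at the summits than 1 kb away, each at a minority of summits. Of 18 motifs, 10 differed between the 200 bp around the IDR summit and a window 1 kb to the side, 7 higher and 3 lower (two-sided exact McNemar test with Benjamini-Hochberg adjustment). The DRE, TATCGATA, which Dref and BEAF-32 bind, was present at 110 summits and 15 flanks (5.48% and 0.748%, adjusted p = 3.74e-18 by the exact test). The BEAF-32 site TCGATA was at 16.7% of summits and 8.57% of flanks, the M1BP site GGTCACACT at 1.6% and 0.349%, Ohler motif 7 at 5.68% and 2.84%, Ohler motif 6 at 4.49% and 2.74%, the CTCF core at 0.748% and 0.15%, and the AT-rich run AAATTTT at 17.8% and 12.7%. Lower at summits were the short Pho site GCCAT (21.3% and 32.3%), the CA repeat (2.29% and 3.94%) and the E-box CAGCTG (6.78% and 8.77%). Summits and flanks were not matched on base composition. These differences, those of GCCAT and AAATTTT among them, may therefore reflect composition and not binding sites. GAGA factor sites (3.39% and 3.24%) and Zelda sites (4.64% and 5.48%) did not differ past the threshold, and the GAGA difference turned negative in each replicate alone (-0.997 percentage points without replicate 4 and -1.15 without replicate 6). Of the 10 calls, those of the DRE, TCGATA, M1BP, Ohler motif 7, AAATTTT and Pho held in each replicate alone. Ohler motif 6, the CA repeat and CAGCTG were not past the threshold in either replicate alone, and the CTCF core was lost without replicate 4. The TATA box was past it in each replicate alone but not in the IDR list, and CATATG and the bicoid site were past it in replicate 4 alone. In the upper 1003 IDR peaks the calls of Ohler motif 6, Ohler motif 7, the CTCF core and the CA repeat were lost, and Ohler motif 6 and the CTCF core were also lost among the strongest of both replicates. Within 50 bp those of M1BP, both Ohler motifs, CAGCTG and the CTCF core were lost, so that the DRE, TCGATA, AAATTTT and Pho kept their calls in each of these settings. The difference of M1BP was 0.698 percentage points without replicate 4 and 1.84 without replicate 6.

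Against other pooled peaks of the same start-site class and similar GC content, 2 of the 18 motifs differed. The AT-rich run AAATTTT was not among them, at 17.8% of IDR summits and 18.2% of matched summits (Fisher's exact test, adjusted p = 0.872). The DRE was at 5.48% of IDR summits and 4.94% of matched summits (Fisher's exact test, adjusted p = 0.841), the M1BP site at 1.6% and 2.09% (adjusted p = 0.829), GAGA factor sites at 3.39% and 1.4% (adjusted p = 0.0008) and Pho sites at 21.3% and 25.5% (adjusted p = 0.02). On the arms the DRE was at 60 of 852 start-site summits, 7.04%, and at 2 of 623 others, 0.321%. Off the arms it was also found away from start sites, at 21 of 266 pericentromeric summits, 7.89% (Wilson 95% interval 5.22 to 11.8), and at 9 of 43 chromosome 4 summits, 20.9% (11.4 to 35.2). No background share was set against these values by part of the genome, so they do not show an excess of the DRE there. Of the same summits, 33 of 266 and 13 of 43 lay in annotated transposable elements, whose copies are not independent.

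Soft-masked sequence and base composition both differed between the IDR peaks and the rest. GC content was 34.2% at IDR summits and 41% at the others. A mean of 25% of bases within 100 bp of IDR summits was soft-masked, against 19.7% for the rest of the pooled list, a difference of 5.3 percentage points (two-sided permutation test over peaks, p = 1e-05, the smallest that 100000 resamples can give). Within 500 bp the difference was 1.07 percentage points (permutation p = 0.00578). When paired on GC content, the difference was not detectable in the parts compared, at -0.526 percentage points for arm start-site peaks (7.34 unpaired) and, counted as other peaks minus IDR peaks, 1.98 for pericentromeric peaks (-3.8 unpaired), with 95% intervals that include 0 for both paired values. Annotated transposable elements went the other way: 62 IDR summits, 3.09%, lay inside one, against 7.12% of the rest (odds ratio 0.416, 95% interval 0.322 to 0.538, two-sided Fisher's exact test, p = 3.93e-14). The overall value mixes parts of the genome and start-site classes that differ in their elements. Reads from near-identical copies of an element may also not be placed uniquely. A lower share is therefore not a clear avoidance of these elements. On the arms the shares were 0.475% of IDR peaks and 2.48% of the rest (odds ratio 0.187, Fisher's exact test, p = 1.21e-08), in pericentromeric parts 9.7% and 13.7% (odds ratio 0.675, p = 0.0209), and on chromosome 4 12.6% and 17.9%, which did not pass (odds ratio 0.66, p = 0.144). Split by distance to a start site, a comparison added after the data were examined, the difference passed only for arm peaks away from start sites (3 of 623 and 387 of 11483, odds ratio 0.139, Fisher's exact test, p = 3.4e-06). It did not pass for arm start-site peaks (odds ratio 0.754, Fisher's exact test, p = 0.812) or for pericentromeric peaks away from start sites (odds ratio 0.88, Fisher's exact test, p = 0.588). Chromosome 4 peaks away from start sites went the other way without passing (13 of 43 and 252 of 1347, odds ratio 1.88, Fisher's exact test, p = 0.0737).

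The replicates shared most of their strongest peaks but a minority of their full lists. Of the 2006 strongest peaks of replicate 4, 1339 had a summit of the 2006 strongest of replicate 6 within 100 bp, 66.7% (Wilson 95% interval 64.7 to 68.8), against a mean of 5.92% when as many peaks were drawn at random from replicate 6. Of the IDR peaks, 1349 were among the strongest of both replicates, 67.2%, with 65.2% on the arms, 71.1% in pericentromeric parts and 78.7% on chromosome 4. Across the 1893 IDR peaks matched in both replicates, the Spearman correlation of signal was 0.711 and the Pearson correlation of log2 signal 0.845. The Spearman correlation was 0.937 across chromosome 4 peaks, 0.837 across pericentromeric peaks and 0.641 across arm peaks. The lower and upper quartiles of IDR signal were 204 and 1308 on chromosome 4, 158 and 792 in pericentromeric parts and 146 and 290 on the arms. A narrower range can by itself lower a correlation, so these values do not rank the parts by agreement. Over the full lists, 10368 of the 30000 calls were matched, 34.6%, with a Spearman correlation of 0.61. These are correlations across peaks, which are not independent replicates.

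**Figure D4:**
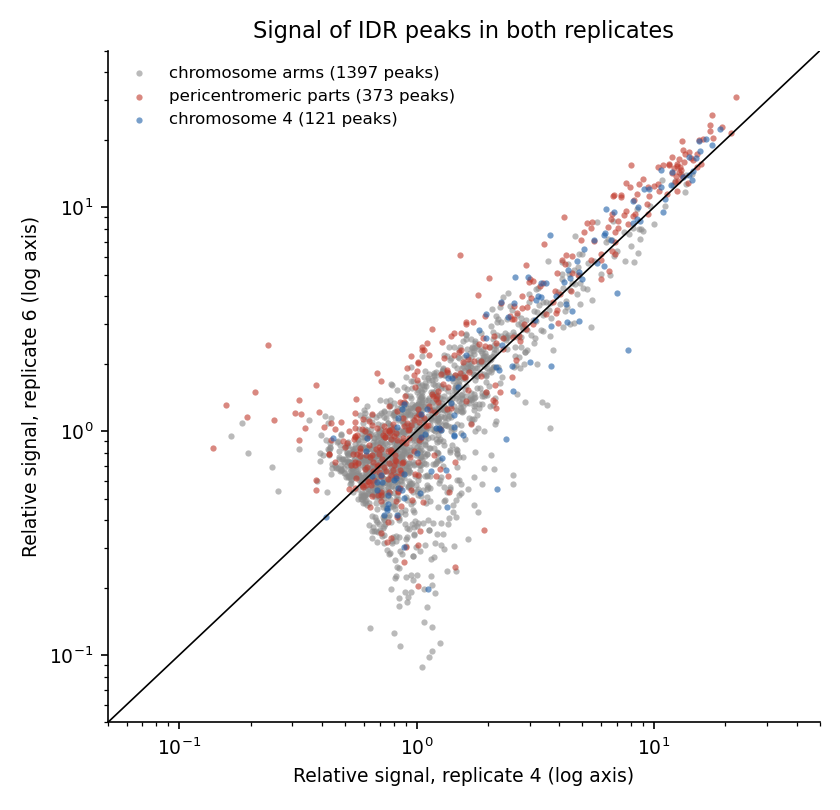
Relative signal (signal value over the median of the 2006 strongest peaks of the same list, log axes) of IDR peaks matched in replicate 4 (x axis) and replicate 6 (y axis), 1 point per peak and the line of equal values; 2 matched peaks on Y are not drawn. The 373 pericentromeric and 121 chromosome 4 peaks follow the line at high signal, with nearly all of the 25 strongest IDR peaks above it. The 1397 arm peaks spread most at low signal.

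At the Su(var)2-HP2 gene itself (FBgn0026427, 2R from 14607154 to 14618118, minus strand) there was 1 IDR peak within 25 kb, and 49.7% of 10000 random genes had fewer. Within 10 kb there was also 1, and 69.1% had fewer. Its summit at position 14618793 lay 675 bp from the Su(var)2-HP2 start site and 22 bp from that of the neighbouring gene Sec61beta, with rank 1328 of 2006. The peak ranked 1020 in replicate 4 and 3772 in replicate 6, so it was not among the strongest of replicate 6.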

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

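Comparisons by gene within each part of the genome, lists on the arms only, signal within each part and a second motif flank were chosen after the data were examined. Of 80 alternative values of the main results, 65 kept their direction and their side of the threshold or stayed within their interval. This total, and that for single lists and motifs below, includes leaving out the surroundings of Su(var)2-HP2. That setting removed 1 of 2006 IDR peaks, so it could hardly change a value. The start-site share, the signal at start sites and the promoter peaks of chromosome 4 and pericentromeric genes did so under each alternative tried. The soft-masked difference did so too but fell to 1.07 percentage points within 500 bp, and pairing on GC content, tried separately on arm start-site and pericentromeric peaks, removed it. The chromosome 4 odds ratio ran from 1.21 to 1.55 with a replicate left out, lost its call at the lower value, and was 1.94 in the upper 1003 IDR peaks. The pericentromeric odds ratio was 1.72 against random places, the opposite direction to the main value; the backgrounds differ, since weak pooled peaks are often pericentromeric. Replicate overlap was 74.9% for any shared base, 60.8% for intervals sharing 0.5 of each, 75.8% for the 1003 strongest peaks and 54.2% for the 4012 strongest. The Spearman correlation was 0.795 in the upper 1003 IDR peaks and 0.61 over all 10368 matched peaks. The number of gene lists past the threshold was 4 among genes with a pooled-list summit and 5 on the arms, where fewer lists and genes were tested. The number of motifs was 6 in the upper 1003 IDR peaks, 5 within 50 bp and 2 against matched pooled peaks. With matched peaks the differences of the BEAF-32 site TCGATA (-0.399 percentage points), M1BP (-0.499) and the AT-rich run (-0.449) turned direction, without a call; the cause was not tested. With the second flank the CAGCTG call was lost (exact McNemar test, adjusted p = 0.102) and the TATA box gained one (adjusted p = 0.0142). The count at Su(var)2-HP2 was 0 in the upper 1003 IDR peaks and 0 to 1 with a replicate left out. For single lists, motifs and gene ranks, 395 of 472 values were the same, 33 lost a call, 17 gained one (among them the Polycomb and Trithorax, neurogenic and dorsoventral lists), 4 moved and 23 turned direction, 20 of these with no call on either side. Of the odds ratios, that of the Hox list turned in the upper 1003 IDR peaks (1.48), in those among the strongest of both replicates (1.08) and with a summit anywhere in the gene (3.04), as did that of heterochromatin proteins (1.31). The piRNA list turned in the same 2 peak sets (0.533 and 0.803), within 250 bp (0.735) and among genes with a pooled-list summit (0.94), and the neurogenic list within 250 bp (0.887). Of the motif differences, in percentage points, GAGA turned in the upper 1003 IDR peaks (-0.499), in those among the strongest of both replicates (-0.222), within 50 bp (-0.499), with the second flank (-0.0499) and with a replicate left out (-1.15 to -0.997). The initiator turned within 50 bp (0.349), the Su(Hw) core among the strongest of both replicates (-0.0741), and Zelda (0.15) and CLAMP (0.598) against matched peaks, where the Su(Hw) core had 0; the cause was not tested. Depth is unknown, so it cannot be said how far it limits the weaker peaks.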

Other observations

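The tRNA, soft-masked sequence (unpaired), low-rank and Su(var)2-HP2 locus tests below were set before their results were seen. The tests of GC-paired peaks, of transposable elements at arm start sites, of tRNA genes with a pooled-list summit and of peak clusters were chosen only after.

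Promoter peaks on the arms were clustered. In the 200 kb from 10200001 to 10400000 of 2L, 29 of 55 groups of start sites had an IDR summit within 500 bp, 52.7%, against 5.76% of all 12813 such groups on the arms. Replicate 4 alone gave 33 and replicate 6 alone 29. The genes there, named after their values were seen, include ClpP (signal value 3063, rank 28), the translational repressor gene me31B (2951, rank 34), Cdk1, Usp14 (2318), CG5056 and the bHLH gene da (1764). The next 200 kb, with RpS27A, Bug22 (1634) and pie, had 11 of 34. Further windows stood out on 2R from 24000001 (13 of 39, with eEF5, tsr, yki and enok) and on X from 15800001 (12 of 35, with MSBP, Gapdh2, shi and exd). Strong arm peaks also lay close beyond the pericentromeric borders, at vlc (2843), Cndp2 (2512) and Fis1 (2110) near 5.6 to 5.7 Mb of 2R.

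Recovery of any heavily transcribed gene would put promoter peaks at arm tRNA genes, and 3 of 290 had one against 1096 of 13672 arm protein-coding genes (odds ratio 0.12, 95% interval 0.0384 to 0.375). Reads from near-identical tRNA copies may be lost. Among genes with any pooled-list summit the counts were 3 of 80 and 1096 of 5069 (odds ratio 0.141, 95% interval 0.0445 to 0.448). Partial loss of reads could itself leave a tRNA gene with only a weak pooled-list call. These counts therefore do not decide on recovery at every kind of transcribed gene. Recovery at highly transcribed protein-coding genes stays open too, since 32 of 87 arm ribosomal protein genes had a promoter peak (odds ratio 6.85). Of the arm proteasome subunit genes, 2 of 48 had one (odds ratio 0.498, Fisher's exact test, adjusted p = 0.519). Chance scatter is argued against by the clusters, since the highest window in 10000 random draws held 13 groups of start sites with a peak. Repeat DNA stays open, as arm start-site IDR summits had 7.34 percentage points more soft-masked sequence than other arm start-site peaks (95% interval 6.22 to 8.46), but it may reflect base composition: paired on GC content the difference was -0.526 (95% interval -1.7 to 0.647), with GC at 33.3% in IDR peaks and 41.1% in the others before pairing, and transposable elements do not decide it, with 4 of 852 summits inside one against 34 of 5470 (odds ratio 0.754, 95% interval 0.267 to 2.13). No biological explanation was tested, as the design has 1 group.

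The pericentromeric share was smaller in IDR peaks than in the rest of the pooled list. Weak calls in repeat DNA stay open. The other pericentromeric summits differed from the IDR summits by -3.8 percentage points of soft-masked sequence (95% interval -6.19 to -1.4). An interval wholly on the negative side had been set beforehand as counting against this explanation, and the result met that rule. When paired on GC content, a test chosen only after, the difference was 1.98 (95% interval -1.26 to 5.22). Base composition may therefore account for the first value. The shares in annotated transposable elements, 13.7% and 9.7%, were 13.9% and 12.4% away from start sites and do not decide it. Replicate noise alone is argued against: of 8567 pericentromeric calls of replicate 4 below rank 2006, 38.2% matched a summit of replicate 6 within 100 bp, 2.09 times the 18.3% found after moving the summits by 2 to 10 kb (95% interval 2.03 to 2.15), with 3.51 on the arms. The interval covers counting error only and treats the calls as independent, although called intervals can hold several summits. The limit set beforehand was a ratio above 2, which the value exceeded only narrowly. A shared control or broad, low enrichment could both give matching low-ranked calls, and neither was tested.

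Extra copies of the tagged gene region in the transgenic line would be a possible explanation for peaks around Su(var)2-HP2. With 1 IDR peak within 25 kb and 49.7% of random genes having fewer, the count is at the median of random genes, but within 10 kb and without replicate 6 the same count lies above a median of 0. The count is below the highest 2.5% of random genes in each of these settings. A count of 1 is too small to decide, so this explanation stays open.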
